A study of Mus musculus with 40 samples.

How the data were processed

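Small RNA was sequenced from brown fat, liver, gastrocnemius muscle and hypothalamus of 10 male mice, in 40 libraries. For each tissue 5 libraries hold the total small RNA (input) and 5 hold the RNA pulled down with streptavidin after its thiol groups had been biotinylated (IP), which makes 8 groups of 5. The authors deposited 1 table of expected counts, an estimated count for each of 1894 mature miRNA entries in each library. Of the positive values 18.9% were whole numbers within 0.001, so a read that matches several entries can be split between them. The counts were rounded to whole numbers, which changed a library total by at most 0.13%. A total of 1613 entries had a count in any library. The submitters' processing notes name fastp for trimming, STAR for alignment to the mouse genome mm10 and featureCounts for counting. Their versions, the miRNA annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Groups, mice and pools were taken from the sample labels, and 0 columns of the table were left without a sample.

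Total counts per library ran from 153036 to 5562487 in the inputs (median 1284131) and from 11928 to 921297 in the IPs (median 222657), a ratio of 5.77 between the medians. Levels are given as counts per 1000000 counted miRNA reads (CPM) or as a percent of them. Log2 fold changes are on the scale of the tests (TMM), so their size and sign can differ from the ratio of such levels. In the liver, miR-191-5p was called higher in the IP at 954 CPM there and 965 CPM in the input. For a group with 0 counts, the fold is a bound taken at 3 counts over the group. For a group with 1 to 3 counts, the ratio is given with its exact 95% interval. Both are on the scale of the tests (TMM), from counts summed over the group, and also given with total count. These are PCR reads without molecular identifiers, so intervals and bounds cover counting error only. All inputs were in sequencing pool 1 and all IPs in pool 2, so the pool and the type of library cannot be told apart.

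The following choices were made before the data were examined: the comparisons, tests, lists, the rule for naming miRNAs and most of the alternatives. Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after filterByExpr by group and scaling by trimmed mean of M values (TMM), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All tests were two-sided. The IP was compared with the input in each tissue from its 10 libraries. The difference of this change between brown fat and each remote tissue was tested as an interaction over 20 libraries. Each tissue's inputs were compared with the mean of the other three tissues over the 20 input libraries. Of the input and IP libraries with the same tissue and replicate number, 19 pairs come from the same mouse by the labels, and brown fat replicate 5 joins mice 8 and 10. After group means were removed, the correlation within these pairs ran from -0.04 to 0.58 with a median of 0.15, was over 0.1 in 13 of the 19, and was highest with the own partner in 12. These values show some pairing, but the mouse had been planned as an alternative replicate block and was not part of the main model.

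A total of 9 lists of miRNAs were fixed from general knowledge: brown fat, liver, striated muscle (myomiRs), brain, red blood cell, leukocyte, endothelium, the let-7 family and the imprinted Dlk1-Dio3 cluster. They were tested in the IP of each tissue with camera and fry of limma 3.58.1, with adjustment over 36 tests. Camera compares a list with the other miRNAs tested, here with a preset correlation of 0.01 between miRNAs. The fry PValue tests whether a list's members move on balance one way, and PValue.Mixed whether they change in either direction; neither compares the list with other miRNAs. A second kind of list was built from the inputs: miRNAs higher in 1 tissue than in each of the tissues apart from the one whose IP was tested, with an adjusted p under 0.05 and a log2 fold change of at least 1. The inputs of the tested tissue took no part in building its lists, and 12 such lists were tested.

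The text names the 8 miRNAs with the largest change in each direction for an IP comparison, 5 in each direction for a difference between tissues and 5 positive ones for an input contrast, among those past the threshold with a mean of at least 100 CPM. It also names up to 4 members of each fixed list, those with the highest mean CPM. Not all miRNAs the rule selects are printed. Exceptions are marked as chosen after their values were seen. Some entries share their reads, as copies or as both strands of a locus: 25 pairs with at least 400 counts had a correlation of log values over 0.995, and counting each once drops 22 entries. Hairpin positions are from the GENCODE annotation of GRCm38 (mm10).

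The alternatives were scaling by the DESeq2 median of ratios inside edgeR (RLE), total count as the only scaling, a minimum mean of 10 CPM, no filter, DESeq2 1.42.0, limma-voom with sample weights, a 2-fold minimum, the replicate block, a fit of all 40 libraries, an estimated correlation in camera, list thresholds of 2 and 3, and leaving out each library in turn. Others were chosen after seeing the data: leaving out hypothalamus input 4 and liver IP 4, counting shared entries once, and rescaling the IPs to an equal median change. The tests were tested on simulated data with 200 changed miRNAs and the depths of these libraries: of 4-fold changes they recovered 100% in the IP comparisons of brown fat, liver and muscle and in the inputs, 48.6% in the hypothalamus IP, and 61.3%, 90% and 38.2% in the differences from liver, muscle and hypothalamus, with at most 2.17% false calls. Of 2-fold changes they recovered 84.6%, 35.7%, 50% and 14.3% in the IP comparisons of brown fat, liver, muscle and hypothalamus, 4%, 24% and 4.5% in the differences and 66.7%, 52.8%, 51.6% and 54.8% in the inputs. The 200 were drawn from all entries with a count, with rises and falls equally likely, so only part of them was tested. In brown fat 26 with 2-fold and 44 with 4-fold changes were among the 321 tested, whereas 244 of 305 were called in the real data. The simulation therefore does not measure errors of scaling where most miRNAs change. TMM scales to 1 reference library, and each library was set as the reference in turn. The labels name no mice without 4TU or without Cre, so no background of the pull-down could be computed. Sequence reads were not used here. Log2 values are rounded to 2 decimals and other values to 3 significant digits.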

Results

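The mice carried a Cre recombinase driven by Ucp1, the uncoupling protein gene of brown fat, and a Cre-dependent transgene for UPRT. This enzyme turns the base 4-thiouracil (4TU) into a nucleotide that new RNA takes up. The mice were 8 to 12 weeks old and received 4TU at 50 mg/kg 4 times, 48 h apart. The question of the pull-down is which miRNAs are labelled in brown fat, and whether labelled miRNAs are found in remote tissues. Each group has 5 libraries. Input totals ran from 968944 to 2121980 counts in brown fat, 675738 to 1129986 in liver, 3750431 to 4726655 in muscle and 153036 to 5562487 in hypothalamus. IP totals ran from 210603 to 817018 in brown fat, 11928 to 444006 in liver, 109978 to 921297 in muscle and 67819 to 229622 in hypothalamus. A library held a median of 651, 488, 573 and 736 miRNAs with at least 1 count in the inputs of brown fat, liver, muscle and hypothalamus, and 383, 186, 252 and 397 in the IPs. The labels give no genotype of the single mice and name no group without 4TU or Cre.

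In the brown fat inputs, mmu-miR-193b-3p, a miRNA of brown adipocyte differentiation, was higher than in the other tissues with a log2 fold change of 7.46 (SE 0.48, adjusted p = 1.17e-09, edgeR). Its level was 506.5 ± 440.1 CPM (SD, n = 5), and library 5 held 1283 CPM against 407 CPM in the next library. Its cluster partner mmu-miR-365-3p rose by 4.47 (SE 0.38), at 993 ± 903 CPM (SD, n = 5), with 2605 CPM in library 5 and 635 CPM in the next. mmu-miR-203-5p, an epithelial miRNA on the brown fat list, differed by 5.62 (SE 0.32). mmu-miR-378a-3p, which is encoded in an intron of the mitochondrial regulator Ppargc1b, made up 11.3% ± 1.71 of counts (SD, n = 5) and was higher by 2.99 (SE 0.41, adjusted p = 2.16e-06). miR-133a-3p, a muscle miRNA, was also higher in brown fat (2.13, SE 0.80, adjusted p = 0.0244), and this was 1.99 with adjusted p = 0.0534 without brown fat input 5 and 3.75 without hypothalamus input 4. Of 444 miRNAs tested, 136 were higher and 154 lower in brown fat. With total count as the scaling these were 230 and 78, and without a filter 185 and 156. Of the brown fat list 21 of 28 were higher and 0 lower, as were all 8 of the leukocyte list, all 4 of the endothelium list and 5 of 7 myomiRs. The myomiR miR-1a-3p was the most abundant miRNA in brown fat inputs 1 and 3, at 27.99% and 16.94% of counts.

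In the liver inputs mmu-miR-122-5p, the main miRNA of hepatocytes, made up 39.9% ± 3.09 of counts (SD, n = 5) and was higher than in the other tissues by 10.27 on the log2 scale (SE 1.00, adjusted p = 2.37e-08). The value was 11.74 without hypothalamus input 4. The other arm of its hairpin, miR-122-3p, differed by 9.48 (SE 0.49; 10.12 without brown fat input 4). miR-192-5p and miR-194-5p, which share a cluster active in gut and liver, differed by 7.52 (SE 0.44) and 5.85 (SE 0.23), and miR-31-5p by 6.05 (SE 0.30). miR-148a-3p, abundant in hepatocytes, differed by 3.66 (SE 0.32). All 12 of the liver list were higher and all 7 myomiRs lower. Of the 444 tested, 101 were higher and 173 lower, and 48 and 248 with total count as the scaling.

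In the muscle inputs mmu-miR-1a-3p, the main miRNA of striated muscle, made up 61.15% ± 1.565 of counts (SD, n = 5) and was higher than in the other tissues by 6.93 (SE 0.85, adjusted p = 6.88e-07); miR-1b-5p, its antisense entry, shares its reads. mmu-miR-196a-5p, a Hox-cluster miRNA of the hind part of the body, differed by 11.17 (SE 0.76, adjusted p = 2.59e-09). miR-133a-5p, miR-133b-3p and miR-206-3p, which are myomiRs, differed by 7.14 (SE 0.69), 6.72 (SE 0.77) and 6.32. Without hypothalamus input 4 the values were 8.45 for miR-1a-3p, 11.80 for miR-196a-5p and 7.80, 7.80 and 7.64 for these myomiRs. miR-378a-3p was higher by 2.12 (SE 0.41, adjusted p = 0.000156), a value of 0.33 with total count as the scaling. All 7 myomiRs and all 7 of the red blood cell list were higher. Of the 444 tested, 99 were higher and 170 lower, against 121 and 141 with RLE, 148 and 165 without a filter, and 26 and 364 with total count.

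In the hypothalamus inputs the neuronal miRNAs stood out. miR-124-3p, found throughout neurons, was higher than in the other tissues by 6.87 (SE 0.24, adjusted p = 1.75e-16), and miR-9-5p, of neurons and their precursors, by 6.36 (SE 0.20). miR-7a-5p, an abundant miRNA of the neuroendocrine hypothalamus, differed by 4.43 (SE 0.27) and miR-127-3p, of the imprinted Dlk1-Dio3 cluster, by 4.76 (SE 0.20). Large differences were those of miR-873a-5p (7.21, SE 0.32, 8.12 without liver input 3; the entry miR-873b shares its reads), miR-1224-5p (7.10, SE 0.40, 7.99 without liver input 2) and miR-760-3p (6.91, SE 0.40). Of the brain list 30 of 31 were higher and of the Dlk1-Dio3 cluster 65 of 66. All 8 leukocyte, 7 red blood cell and 4 endothelium miRNAs were lower. Of the 444 tested, 225 were higher and 151 lower, against 300 and 69 with total count and 421 and 175 without a filter.

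The fixed lists had these further counts in the inputs. The let-7 family was higher and lower for 8 and 1 of 17 in brown fat, 9 and 1 in liver, 3 and 8 in muscle, and 3 and 10 in hypothalamus. Adjusted over the list alone, the counts differed in these lists: 7 and 1 for let-7 and 3 and 21 for brain in brown fat (3 and 20 over all), 0 and 23 for brain (0 and 22) and 2 and 56 for Dlk1-Dio3 (1 and 54) in liver, 11 and 30 for Dlk1-Dio3 in muscle (11 and 29), and 0 and 7 for liver (0 and 9) and 0 and 0 for myomiRs (0 and 3) in hypothalamus. In brown fat the liver list had 0 and 5, red blood cells 3 and 0, and Dlk1-Dio3 0 and 51. In liver the brown fat list had 8 and 6 of 28, red blood cells 0 and 4, leukocytes 6 and 2, and endothelium 0 and 0 of 4. In muscle the brown fat list had 10 and 9, liver 0 and 9, brain 2 and 24, leukocytes 1 and 1, and endothelium 4 and 0. In hypothalamus the brown fat list had 3 and 19.

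In brown fat the IP was compared with the input to find which miRNAs were enriched in the pull-down. Without a group lacking 4TU or Cre, a rise cannot be read as labelling in the cells where the driver is active. mmu-let-7a-5p, a let-7 member of differentiated tissues, rose from 6407 ± 939 CPM in the input to 60360 ± 19080 CPM in the IP (SD, n = 5 each). Its TMM-scaled log2 fold change was 4.27 (SE 0.31, adjusted p = 6.02e-09), more than these levels give. mmu-miR-29a-3p, which acts on matrix and metabolic genes, fell from 26100 ± 12310 to 494 ± 143 CPM (-4.59, SE 0.32, adjusted p = 5.92e-09). mmu-miR-378a-3p went from 11.3% ± 1.71 of counts to 12.7% ± 3.5 and rose by 1.23 (SE 0.28, adjusted p = 0.000652), but with total count as the scaling the value was 0.17 (adjusted p = 0.616). miR-30c-5p, a miRNA that promotes brown fat genes, fell (-1.49, SE 0.31, adjusted p = 0.000278). miR-5099 rose by 5.02 (SE 0.38), the most among miRNAs with a mean of at least 100 CPM. let-7d-5p (4.14, SE 0.33), miR-676-3p (4.07, SE 0.29), miR-423-5p (3.88, SE 0.31), miR-320-3p (3.87, SE 0.25) and let-7f-5p (3.84, SE 0.35) rose too. miR-15a-5p, a cell-cycle miRNA, had 3 counts in the IPs and 2833 in the inputs, 123-fold lower (95% interval 42.2 to 599) and 267-fold with total count. miR-29c-3p (-5.75, SE 0.62), miR-29b-3p (-5.30, SE 0.46), miR-19b-3p (-5.07, SE 0.56; -5.92 without IP 2) and the red blood cell miR-451a (-4.98, SE 0.72; -4.26 without input 5) also fell.

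Among miRNAs on the lists of other tissues, the myomiR miR-206-3p rose in the brown fat IP (2.82, SE 0.53, adjusted p = 0.000126). miR-133a-3p fell (-1.74, SE 0.56, adjusted p = 0.00863), a call lost with all 40 libraries at -1.92. The myomiR miR-1a-3p was the most abundant miRNA of brown fat IPs 1, 3 and 4, at 21.37%, 21.12% and 23.82% of counts. Its source in brown fat was not tested. mmu-miR-1a-3p had 1.28 (SE 0.54, adjusted p = 0.0379), a call that was lost with RLE (0.98), total count (0.22), DESeq2 (0.98) and all 40 libraries (1.16). Without brown fat input 1 it was 1.91. It was also lost without brown fat input 2 (1.05), 3 (1.32), 4 (1.15) or 5 (1.06) and without IP 1 (1.16), 3 (1.17) or 4 (1.17). The hepatocyte miRNAs miR-192-5p (-1.34, SE 0.31) and miR-148a-3p (-1.19, SE 0.30) fell. mmu-miR-122-5p, chosen after its values were seen, rose from 173 ± 30.3 to 983 ± 249 CPM (SD, n = 5 each; 3.56, SE 0.27, adjusted p = 8.34e-09). The brain miRNA miR-7b-5p fell (-4.03, SE 0.28), miR-128-3p had -0.04 (SE 0.37, adjusted p = 0.927; called with total count at -1.12) and the leukocyte miR-146a-5p -0.46 (SE 0.26, adjusted p = 0.111; called with RLE at -0.79, total count at -1.65, DESeq2 at -0.79 and no filter at -0.90). Endothelial miR-126a-3p fell (-3.25, SE 0.29) and miR-486a-5p, on the red blood cell list but also high in the muscle inputs, rose (2.63, SE 0.33). In the Dlk1-Dio3 cluster miR-127-3p fell (-1.38, SE 0.28) and miR-541-5p rose (2.30, SE 0.31). Of 305 miRNAs tested 112 were higher and 132 lower in the IP. With RLE these were 91 and 149, and with total count 55 and 174.

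In the liver IP mmu-miR-122-5p went from 39.9% ± 3.09 to 76.3% ± 3.64 of counts (SD, n = 5 each). Its TMM-scaled log2 fold change was 2.51 (SE 0.55, adjusted p = 0.000228), more than these shares give. miR-192-5p (-2.46, SE 0.45) and miR-148a-3p (-2.30, SE 0.48), also of hepatocytes, fell. miR-194-2-3p of the liver list, chosen after its values were seen, rose (2.90, SE 0.35). In the fit of all 40 libraries miR-122-5p had 2.27 with adjusted p = 0.0523. mmu-let-7a-5p rose from 4838 ± 1160 to 41940 ± 5378 CPM (4.66, SE 0.52) and mmu-miR-29a-3p fell from 6542 to 119 CPM (-4.49, SE 0.47, adjusted p = 6.88e-09). mmu-miR-1a-3p, the muscle miRNA, rose from 833 ± 189 to 3777 ± 6683 CPM (2.32, SE 0.46, adjusted p = 7.21e-05), and of the IP libraries number 4, with 11928 counts in all, held 15719 CPM against 1274 in the next; without it the rise was 1.61. miR-206-3p rose (3.84, SE 0.47) at 32 counts in the IPs, and was not tested when any of the 5 liver inputs was left out. The myomiR miR-133a-3p, with 1 count in the IPs and 197 in the inputs, was 12.1-fold lower (95% interval 2.14 to 480) and 40.4-fold with total count. Its mean level was 10.6 CPM in the IPs, of which 4 of 5 lay below all inputs, and 42.5 CPM in the inputs. miR-378a-3p had -0.69 (SE 0.41, adjusted p = 0.127), and was called lower without any of liver inputs 1 to 5 (-1.59, -1.63, -1.31, -1.52 and -1.39) and without IP 3 (-1.08). It was also called with RLE (-1.57), total count (-2.10), no filter (-1.40), a minimum of 10 CPM (-1.73), DESeq2 (-1.56), limma-voom (-0.79) and shared entries once (-1.55).

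Among miRNAs with a mean of at least 100 CPM, the largest rises in the liver IP were those of mmu-miR-5119 (7.10, SE 0.65) and mmu-miR-6236 (5.44, SE 0.60). In CPM, library 4 was highest for both, with 2140 of miR-5119 against 68.3 in the next library and 3912 of miR-6236 against 291, and without it the changes were 6.16 and 4.67. Both reached the mean of 100 CPM, and thus this ranking, only through library 4. mmu-miR-423-5p (4.83, SE 0.41, adjusted p = 3.46e-10), let-7d-5p (4.45, SE 0.49), let-7e-5p (4.00, SE 0.46) and miR-125a-5p (3.89, SE 0.42) rose too; library 4 held 8467 CPM of miR-423-5p and the next 1905. miR-29b-3p (1 count against 1288) was 79-fold lower (95% interval 14.2 to 3120; 264-fold with total count) and miR-455-5p, of the brown fat list (2 against 1281), 39.3-fold lower (10.9 to 325; 131-fold with total count). miR-16-5p (-5.15, SE 0.60), miR-340-5p (-4.53, SE 0.55), miR-101a-3p (-4.29, SE 0.54), miR-30e-5p (-4.07, SE 0.47), miR-30c-5p (-2.10, SE 0.41) and miR-126a-3p (-2.59, SE 0.43) fell, and miR-486a-5p rose (3.20, SE 0.44). Of 200 miRNAs tested 57 were higher and 92 lower. The split was 41 and 127 with RLE, 29 and 135 with total count, 47 and 149 with a minimum of 10 CPM, 37 and 116 with shared entries once, and 42 and 126 with DESeq2.

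The size of the changes in the liver IP moved when 1 library was left out, though no call named in this part was lost. The lower ends of the ranges lay below the reported values for rises and falls alike. With no library left out, RLE moved the median change by -0.94, and the choice of the TMM reference moved the changes by -0.77 to 0.47. Part of these ranges can thus come from the scaling and not from the library left out. Without 1 library, the rises ran from 3.86 to 4.87 for let-7a-5p, 3.62 to 4.65 for let-7d-5p, 3.25 to 4.17 for let-7e-5p, 4.24 to 4.92 for miR-423-5p, 3.18 to 3.94 for miR-125a-5p, 2.39 to 3.54 for miR-486a-5p and 1.72 to 2.74 for miR-122-5p. The falls ran from -5.42 to -4.32 for miR-29a-3p, -6.22 to -4.78 for miR-16-5p, -6.24 to -4.26 for miR-340-5p, -5.35 to -4.03 for miR-101a-3p and -5.16 to -3.92 for miR-30e-5p. They ran from -3.28 to -2.32 for miR-192-5p, -3.24 to -2.12 for miR-148a-3p, -3.02 to -1.93 for miR-30c-5p and -3.54 to -2.41 for miR-126a-3p. The fitted value reached -10.24 for miR-29b-3p without IP 5 and -10.19 for miR-455-5p without IP 3.

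In the muscle IP mmu-let-7a-5p rose from 1059 ± 106 to 40270 ± 14820 CPM (SD, n = 5 each; 6.09, SE 0.49, adjusted p = 9.18e-11); IP library 5 held 66180 CPM against 37080 in the next. mmu-miR-29a-3p fell from 3291 to 54.7 CPM (-5.43, SE 0.34, adjusted p = 1.19e-12). mmu-miR-1a-3p was not called (0.90, SE 0.55, adjusted p = 0.132) at 61.15% of counts in the input and 55.6% ± 5.782 in the IP, where library 5 was lowest with 453277 CPM against 571820; without that library it was 1.04 with adjusted p = 0.00526. The myomiR mmu-miR-206-3p rose from 4099 ± 800 to 18540 ± 3526 CPM (3.16, SE 0.46, adjusted p = 9.89e-07) and miR-133a-3p fell (-1.77, SE 0.35, adjusted p = 5.57e-05). mmu-miR-196a-5p, high in this muscle and also on the brown fat list, rose from 178 ± 52.3 to 2194 ± 990 CPM (4.41, SE 0.38, adjusted p = 1.72e-10). mmu-miR-122-5p, of hepatocytes, rose from 170 ± 192 to 1697 ± 1720 CPM (4.56, SE 0.85, adjusted p = 3.2e-05). Its change was 5.67 without muscle input 1 and 3.09 without muscle IP 1, which come from the same mouse by the labels. miR-378a-3p fell (-0.86, SE 0.37, adjusted p = 0.0344), a call lost without muscle input 1 (-0.61), 2 (-0.64) or 3 (-0.66) or IP 3 (-0.85) or 4 (-0.84), with a minimum of 10 CPM (-0.70), with all 40 libraries (-0.69), with shared entries once (-0.78) and with a 2-fold minimum.

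Among the other large changes in the muscle IP, let-7e-5p (5.72, SE 0.39), miR-423-5p (5.55, SE 0.40, adjusted p = 1.21e-11), let-7d-5p (5.26, SE 0.42) and miR-320-3p (4.66, SE 0.33) rose. miR-16-5p had 3 counts in the IPs and 5515 in the inputs, 103-fold lower (95% interval 35.3 to 500) and 215-fold with total count. miR-30e-5p (-6.64, SE 0.39), miR-101a-3p (-6.59, SE 0.44), miR-101b-3p (-4.26, SE 0.39; -4.85 without IP 1) and miR-30a-5p (-4.25, SE 0.37) fell, as did the brown fat miRNA miR-30c-5p (-3.64, SE 0.35), the brain miRNAs miR-7b-5p (-4.00, SE 0.33) and miR-9-5p (-3.05, SE 0.35) and endothelial miR-126a-3p (-3.91, SE 0.33). miR-486a-5p (3.77, SE 0.37, adjusted p = 2.01e-09) and miR-541-5p (2.62, SE 0.33) rose. Of 268 miRNAs tested 77 were higher and 151 lower, and 57 and 161 with total count.

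In the hypothalamus IP mmu-let-7a-5p rose from 5284 ± 1539 to 131600 ± 47220 CPM (SD, n = 5 each; 5.39, SE 0.47, adjusted p = 1.65e-06), miR-423-5p by 5.62 (SE 0.56, adjusted p = 3.83e-06) and let-7e-5p by 5.58 (SE 0.52). The neuronal mmu-miR-9-5p fell from 90650 ± 49350 to 14220 ± 6270 CPM (-1.79, SE 0.39, adjusted p = 0.00131). miR-7b-5p was not called (0.28, SE 0.72, adjusted p = 0.728). miR-382-5p and miR-541-5p of the Dlk1-Dio3 cluster rose (3.32, SE 0.40 and 1.88, SE 0.32) and miR-127-3p fell (-2.04, SE 0.47). miR-153-3p, a miRNA of synaptic genes, had 0 counts in the IPs and 3935 in the inputs, at least 68.8-fold lower, or 114-fold with total count. miR-3071-5p, which shares reads with miR-136-3p, had 3 counts against 17112, 299-fold lower (95% interval 102 to 1450) and 495-fold with total count. miR-101a-3p (-7.40, SE 0.55), miR-136-3p (-7.33, SE 0.67; -8.35 without IP 5), miR-137-3p (-6.64, SE 0.88; -7.61 without IP 3) and miR-381-3p (-6.54, SE 0.57) fell, and miR-664-5p (5.33, SE 0.66; 4.68 without IP 1) and miR-92b-5p (5.27, SE 0.54) rose. miR-30c-5p (-3.21, SE 0.40) and miR-126a-3p (-4.11, SE 0.52) fell and miR-486a-5p (3.22, SE 0.56) and the leukocyte miR-146a-5p (2.24, SE 0.56, adjusted p = 0.00287) rose.

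The miRNAs of other tissues in the hypothalamus comparison depended on input 4 and on the model. That library held 17083 CPM of mmu-miR-122-5p against 323 in the next, 178996 of mmu-miR-1a-3p against 2475, and 11232 of mmu-miR-378a-3p against 2086. With it, miR-122-5p had -1.88 (SE 1.43, adjusted p = 0.246), miR-206-3p -1.04 (SE 1.44, adjusted p = 0.517), miR-1a-3p -4.09 (SE 1.54, adjusted p = 0.0276), miR-133a-3p -6.71 (SE 2.0, adjusted p = 0.0086) and miR-378a-3p -2.41 (SE 0.82, adjusted p = 0.017). Without it, miR-122-5p was 2.86 (adjusted p = 0.000849), miR-206-3p 3.31 (adjusted p = 0.000443), miR-1a-3p 0.82 (adjusted p = 0.0861), miR-133a-3p -1.46 (adjusted p = 0.0793) and miR-378a-3p -0.70 (adjusted p = 0.123). With input 4 kept and the mouse as a replicate block, they were 2.17 (adjusted p = 0.0446) for miR-122-5p, 2.04 (0.0666) for miR-206-3p and 0.07 (0.951) for miR-1a-3p. With limma-voom they were 2.85 (adjusted p = 0.028), 2.63 (0.0582) and 0.21 (0.877). The miR-1a-3p call was also lost when any of the 5 IP libraries was left out (-4.17 to -3.98). Of 273 miRNAs tested 77 were higher and 129 lower, and 53 and 153 with total count.

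**Figure D1:**
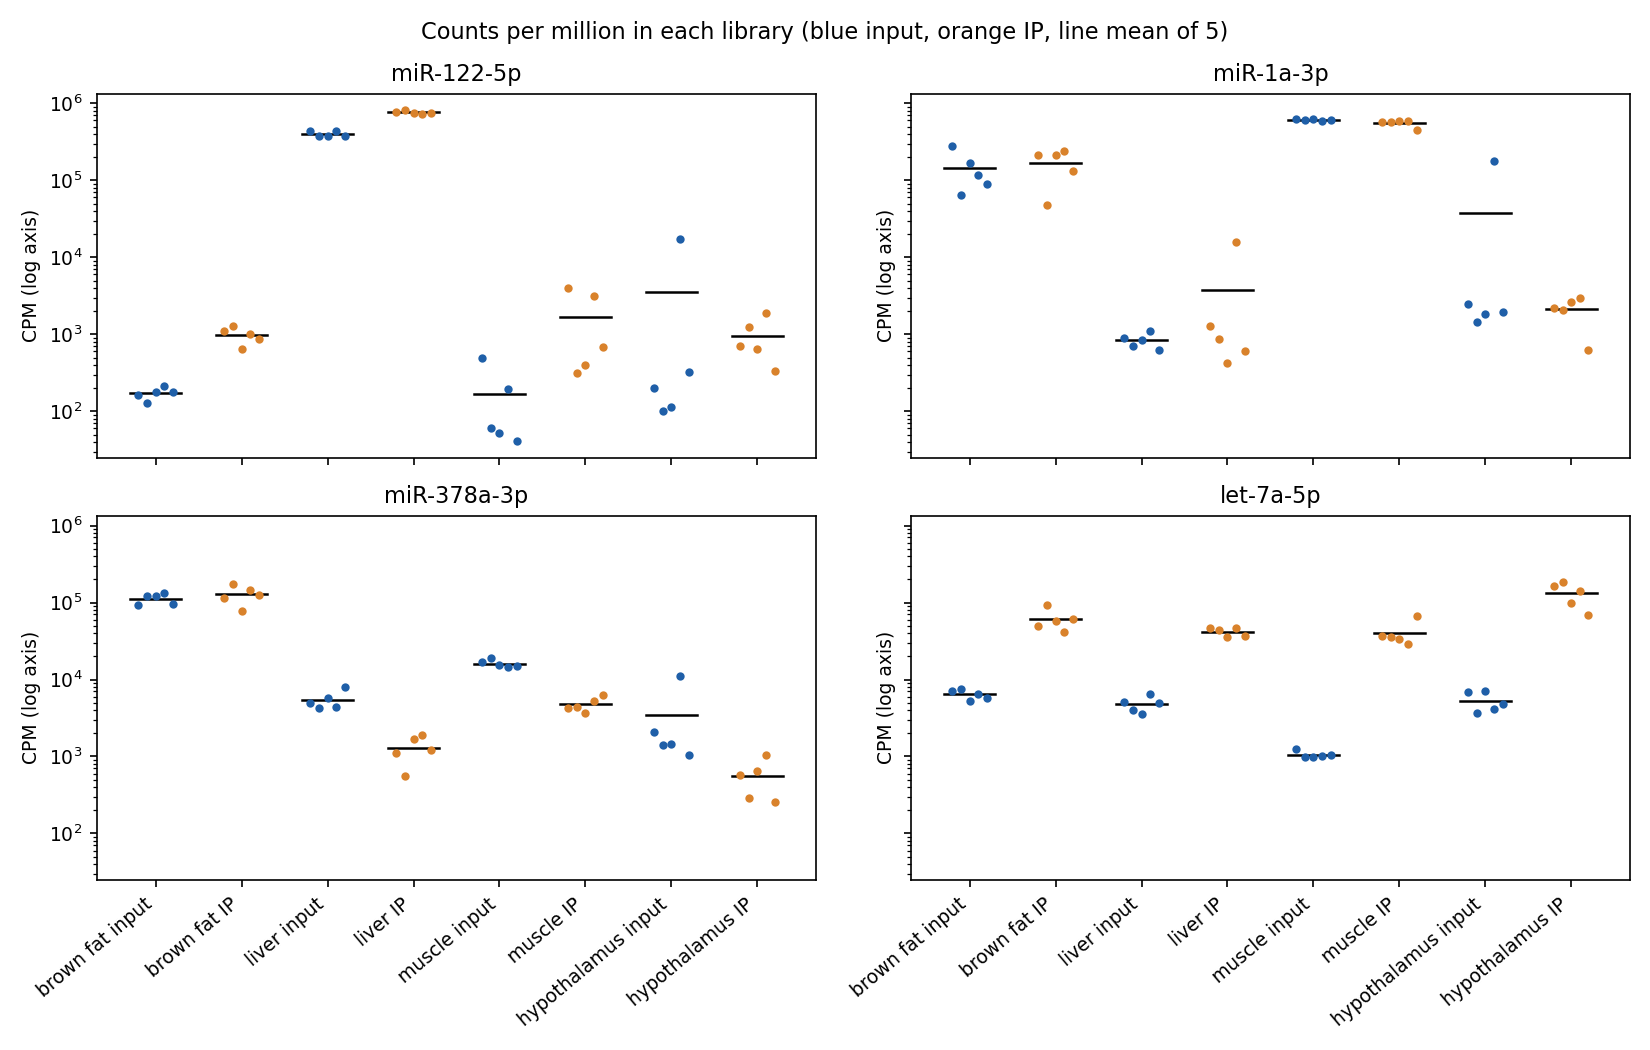
CPM on a log axis for mmu-miR-122-5p, mmu-miR-1a-3p, mmu-miR-378a-3p and mmu-let-7a-5p in the 8 groups, with inputs in blue, IPs in orange, 1 point per library and a line at the mean of 5. let-7a-5p is higher in the IP of every tissue, and hypothalamus input 4 lies above the other 4 inputs for miR-122-5p, miR-1a-3p and miR-378a-3p.

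Relative to TMM, RLE moved the median change of all tested miRNAs by -0.33, -0.94, -0.54 and -0.16 in brown fat, liver, muscle and hypothalamus, and total count by -1.10, -1.62, -0.88 and -0.80. The medians with TMM were -0.34, -0.78, -1.41 and -1.04. Of the fixed lists, the let-7 family rose in the IP of every tissue: 15 of 17 members in brown fat, 15 of 15 in liver, 15 of 16 in muscle and 11 of 13 in hypothalamus were higher, with medians of 3.02, 2.81, 3.61 and 3.63. The camera adjusted p was 2.62e-05, 1.81e-06, 1.81e-06 and 2.77e-06, and adjusted p = 0.631 with an estimated correlation in each. With total count 11, 8, 14 and 11 members were higher. The red blood cell list had 4 higher and 1 lower in brown fat (adjusted p = 0.176) and muscle (0.0567) and 4 higher and 0 lower in liver (0.00694) and hypothalamus (0.0368), where the call was lost with adjusted p = 0.631 with an estimated correlation. Those 4 are the miR-486a and miR-486b entries, which share their reads and were also on a muscle list built from the inputs. miR-451a of the same red blood cell list fell in the brown fat IP, so the rises are those of miR-486 and not of the list as a whole. The endothelium list, the entries of miR-126a and miR-126b that also share reads, had 4 of 4 lower in each tissue (adjusted p = 0.069, 0.187, 0.167 and 0.112). Without 1 library the let-7 call held in each tissue, while the red blood cell call was lost in liver without IP 1 (adjusted p = 0.0565) or 4 (0.109) and in hypothalamus without input 1 (0.0545) or 2 (0.0552). In muscle it was gained without any of the 5 inputs (0.0215 to 0.026). Counts adjusted over the list alone were equal to these for all 9 lists in all 4 tissues.

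The tissue lists were not called by camera in any IP. The brown fat list had 12 members higher and 8 lower of 28 in brown fat (adjusted p = 0.198), 5 and 7 of 19 in liver (0.961), 10 and 10 of 24 in muscle (0.182) and 4 and 6 of 13 in hypothalamus (0.989). Its median was 0.38 in brown fat but -0.70 with total count, and in liver 0.31 with a mean of -0.67 and a median of -0.48 with RLE. The liver list had 1 and 6 of 7, 2 and 8 of 10, 1 and 5 of 6 and 0 and 5 of 6 (0.227, 0.339, 0.336 and 0.182). The myomiRs had 3 and 4 of 7, 3 and 1 of 4, 1 and 4 of 7 and 0 and 3 of 4 (0.989, 0.182, 0.931 and 0.961); camera put them upward in brown fat and hypothalamus, where the medians were -1.74 and -4.09. The calls in hypothalamus depended on input 4, without which 1 of 4 was higher and 0 lower at a median of 0.81. In muscle camera put the brown fat list upward at a median of -0.15, and in hypothalamus downward at 0.66 above the median of all. The brain list had 3 and 9 of 14, 0 and 4 of 7, 0 and 10 of 10, and 3 and 14 of 26 (0.176, 0.182, 0.086 and 0.264). Leukocytes had 0 and 4 of 8, 0 and 3 of 4, 1 and 3 of 6 and 2 and 0 of 2 (0.438, 0.208, 0.539 and 0.264), and Dlk1-Dio3 7 and 15 of 25, 3 and 8 of 15, 5 and 18 of 28 and 13 and 26 of 49 (0.176, 0.217, 0.264 and 0.356). With members of 3 counts or fewer in a group set at 3 counts, the medians of leukocytes in liver and of brain, leukocytes and Dlk1-Dio3 in muscle were -1.62, -1.94, -1.32 and -1.74.

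With 1 library left out, camera still called none of these tissue lists, but medians and counts moved. The median of the brown fat list in liver fell below 0 (-0.97 to -0.02) without any of inputs 1 to 5 or without IP 1, 3 or 5, and 2 or 3 members were then higher without an input. In muscle it was above 0 (0.20 to 0.69) without any of inputs 1 to 5 or without IP 5. Leaving out any muscle input left 5 members of the brain list tested, 4 of them lower, and 17 or 18 of Dlk1-Dio3, 3 of them higher and 12 or 13 lower. Without muscle input 1, 2, 4 or 5 leukocytes had 1 higher and 0 lower of 2. The brain list in liver had 7 of 9 lower without IP 5, and Dlk1-Dio3 in hypothalamus 8 higher and 26 lower without input 3. fry, which does not compare a list with other miRNAs, called 32 of the 36 tests on balance one way and 34 in either direction. The 4 uncalled one way were the myomiRs in brown fat (adjusted p = 0.74) and hypothalamus (0.739) and the brown fat list in liver (0.0767) and muscle (0.851). The let-7 and red blood cell lists were upward in every tissue, and the brain, liver, endothelium and Dlk1-Dio3 lists downward.

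The let-7 members, miR-423-5p and miR-320-3p rose and miR-29a-3p, miR-16-5p and miR-101a-3p fell in each comparison that names them here. Over miRNAs tested in a pair of tissues, the log2 fold changes of IP against input had a Pearson r of 0.81 to 0.93 and a Spearman rho of 0.86 to 0.95; these are correlations across miRNAs, which are not independent replicates. Of 156 miRNAs tested in all 4 tissues, 33 were higher in every IP, where independent calls would give 1.2, and 53 were lower, where they would give 7.1. With shared entries counted once these were 30 and 49. Calls in opposite directions numbered 7 between brown fat and hypothalamus, 2 between brown fat and muscle, 1 between brown fat and liver, 2 between liver and hypothalamus and 0 in the other pairs.

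**Figure D2:**
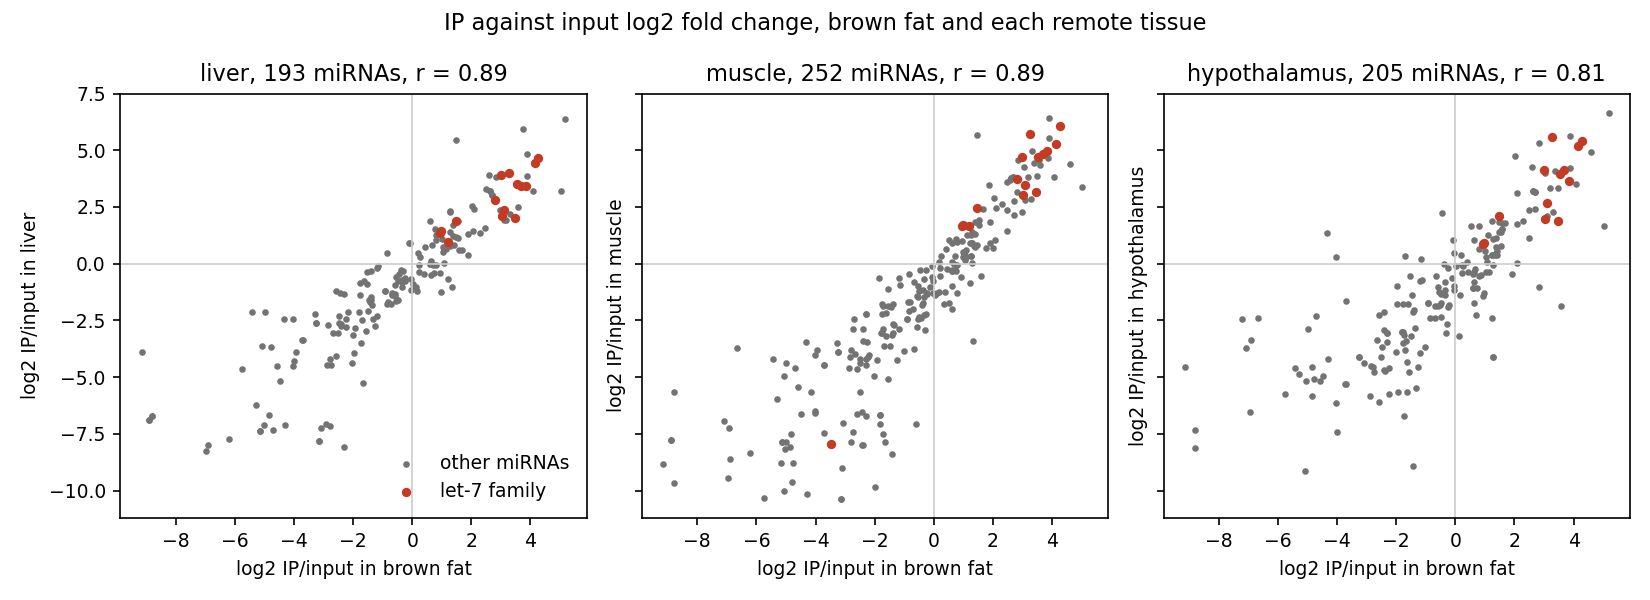
Log2 fold change of IP against input in brown fat (horizontal) against liver (193 miRNAs, r = 0.89), muscle (252 miRNAs, r = 0.89) and hypothalamus (205 miRNAs, r = 0.81), with 1 point per miRNA, the let-7 family in red and other miRNAs in grey. The points run along a rising line in each panel, with most of the let-7 family at its upper end.

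The lists of brown fat miRNAs built from the inputs ask whether miRNAs of brown fat are in excess in the IP of a remote tissue. As the changes were correlated between tissues (Pearson r 0.81 to 0.93), a list median also reflects which miRNAs every IP favours. The lists were not set against their own change in the brown fat IP, and the smallest excess they could show was not measured. The values below thus describe the lists within each IP and cannot decide whether RNA came from brown fat. In the liver IP 6 of the 25 tested members were higher and 14 lower, with a median of -1.29, which was -0.50 relative to all miRNAs (camera adjusted p = 0.503). In the muscle IP 9 of 48 were higher and 31 lower, with a median of -2.08, or -0.67 relative to all (adjusted p = 0.313); the median was -1.94 with members of 3 counts or fewer set at 3 counts. The muscle list holds miRNAs that muscle itself makes, among them mmu-miR-133a-3p at 25120 CPM and mmu-miR-206-3p at 4099 CPM in the muscle inputs, and 4 of the 9 are miR-486 entries that share reads. In the hypothalamus IP 2 of 9 were higher and 5 lower, with a median of -1.38, or -0.33 relative to all (adjusted p = 0.735). fry, without a comparison with other miRNAs, called these lists downward in liver (adjusted p = 0.00432) and muscle (6.54e-06) but not in hypothalamus (0.178), and all 3 in either direction (1.37e-09, 1.37e-09 and 3.44e-07). With an estimated correlation the camera adjusted p was 0.856 in each, and the counts adjusted over the list alone were equal. The mean score of the list minus that of all miRNAs, taken per mouse, was -0.52 ± 0.35 in liver, -0.79 ± 0.10 in muscle and -0.42 ± 0.38 in hypothalamus (SD, n = 5 mice each), above 0 in 0, 0 and 1 mice. miR-378a-3p, the most abundant of the brown fat list, was in the remote IPs at 1.02% ± 0.421 (liver), 3.77% ± 0.8 (muscle) and 0.441% ± 0.251 (hypothalamus) of its mean CPM in the brown fat IP (SD, n = 5 each).

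**Figure D3:**
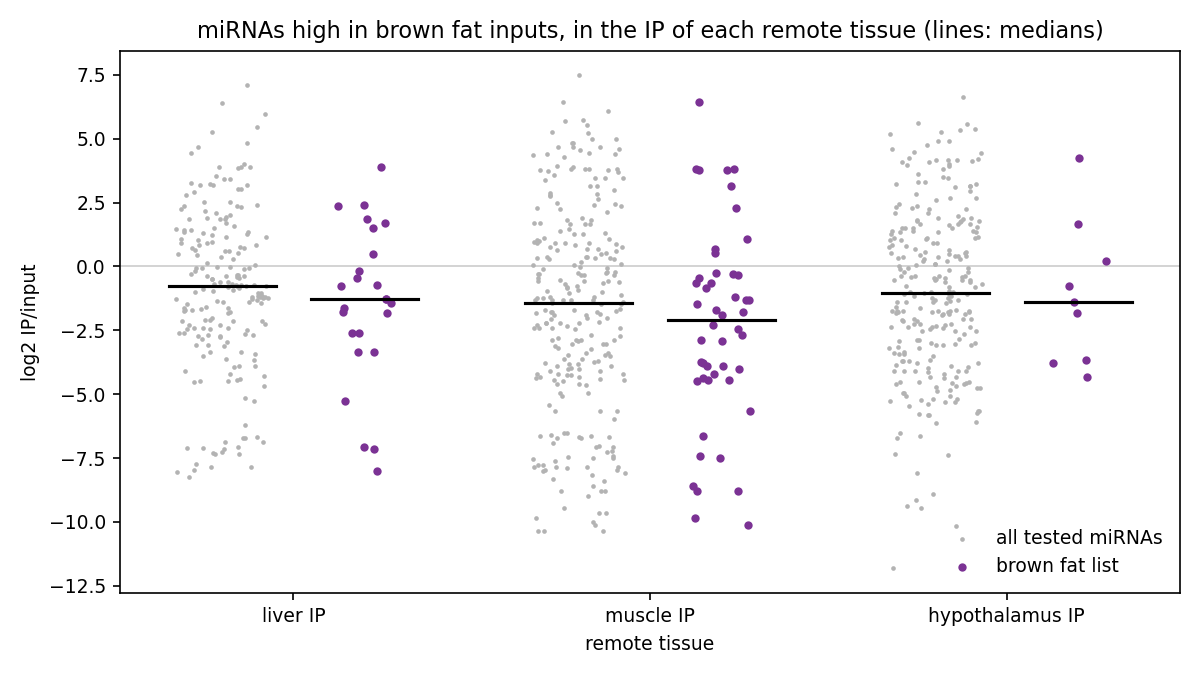
Log2 fold change of IP against input in the 3 remote tissues for all tested miRNAs (grey) and for the brown fat list built from the inputs (purple), with 1 point per miRNA and a black line at each median. The list medians are -1.29, -2.08 and -1.38 against -0.78, -1.41 and -1.04 for all miRNAs in liver, muscle and hypothalamus.

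The tests of the difference ask which miRNAs changed more in the brown fat IP than in the IP of a remote tissue. Against liver, miR-379-5p of the Dlk1-Dio3 cluster changed more in brown fat by 2.64 (SE 0.49, adjusted p = 0.00294), a call lost only with all 40 libraries (2.45, adjusted p = 0.0607) and at 2.01 to 2.74 without 1 library. miR-378a-3p differed by 2.33 (SE 0.53, adjusted p = 0.0125), a call lost without liver input 3 (1.87) or 5 (1.76), without brown fat IP 4 (1.72), with no filter (1.74), with all 40 libraries (2.12) and with equal median change (1.52). miR-6236 differed by -3.55 (SE 0.86, adjusted p = 0.018), a call lost without liver IP 4 (-3.19, adjusted p = 0.0513), liver input 5 (-4.34), brown fat input 1 (-3.21) or brown fat IP 2 (-4.34) or 4 (-4.27) and with all 40 libraries (-4.29). miR-122-5p (1.46, SE 0.57, adjusted p = 0.103) and miR-1a-3p (-0.63, SE 0.75, adjusted p = 0.653) were not called, though miR-122-5p was with total count (1.57, adjusted p = 0.00317). Of 308 miRNAs tested 25 differed upward and 1 downward (77 at an unadjusted p under 0.05). This count was 3, 6, 20, 14 and 4 without brown fat inputs 1 to 5, 4, 4, 2, 4 and 1 without liver inputs 1 to 5, 5, 2, 5, 1 and 4 without brown fat IPs 1 to 5, and 3, 5, 32, 2 and 7 without liver IPs 1 to 5. With DESeq2 the split was 11 and 20, and with equal median change 1 and 5.

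Against muscle, miR-30e-5p (3.82, SE 0.56) and miR-30a-5p (2.83, SE 0.39), miRNAs of a widely expressed family, fell less in the brown fat IP, and let-7e-5p (-2.74, SE 0.40), let-7a-5p (-2.06, SE 0.42, adjusted p = 0.0015) and miR-423-5p (-1.90, SE 0.43, adjusted p = 0.00325) rose less. The adjusted p of miR-30e-5p, miR-30a-5p and let-7e-5p was 4.02e-05, and all 5 calls held in each alternative and with any library left out. miR-378a-3p differed by 1.91 (SE 0.41, adjusted p = 0.00205), which was lost only with all 40 libraries. miR-122-5p (-1.10, SE 0.97, adjusted p = 0.452) and miR-1a-3p (0.16, SE 0.74, adjusted p = 0.889) were not called. Of 324 miRNAs tested 41 differed upward and 27 downward. Without muscle input 4 the count was 45, and the split was 31 and 30 with RLE, 14 and 54 with equal median change and 39 and 8 without a filter.

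Against hypothalamus, miR-7b-5p, a miRNA of neuroendocrine cells, fell in the brown fat IP (61 counts against 7602 in the input) and was not called in the hypothalamus IP (32926 against 638360), a difference of -6.19 (SE 0.82, adjusted p = 1.47e-05). miR-101b-3p differed the other way (1.90, SE 0.62, adjusted p = 0.022), with 895 counts against 24959 in brown fat and 52 against 45329 in hypothalamus. Both calls held in each alternative and with any library left out, at -6.34 to -2.28 and 1.81 to 5.52. miR-378a-3p (1.44, SE 0.77, adjusted p = 0.163), miR-122-5p (3.01, SE 1.42, adjusted p = 0.108) and miR-1a-3p (2.99, SE 1.49, adjusted p = 0.131) were not called, and with the replicate block the latter were -0.30 and -0.63. Of 422 miRNAs tested 145 differed, 9 upward and 136 downward, but the direction of this split is set by the scaling: it was 23 and 36 with RLE, 29 and 13 with total count and 17 and 36 with equal median change. It stayed mostly downward only without brown fat input 4 (7 and 126), hypothalamus input 3 (11 and 132) or brown fat IP 4 (9 and 106). Leaving out any of the other 17 libraries turned it mostly upward, to 196 and 1 without brown fat IP 5. The same 17 omissions made miR-378a-3p (up to 5.19, 3.26 without hypothalamus input 4) and miR-122-5p (up to 7.10, 2.18 without that input) pass the test, and 16 of them miR-1a-3p (up to 6.88, but 1.74 without that input).

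Hairpins of the named miRNAs lie at these places in GRCm38. Mir122 is on chromosome 18 from 65248861 to 65248926 and overlaps an exon of a long non-coding RNA, and Mir378a is on chromosome 18 from 61397835 to 61397900 in an intron of Ppargc1b. Mirlet7a-1 is on chromosome 13 from 48538179 to 48538272, beside Mirlet7f-1 (48537829 to 48537917) and Mirlet7d (48536012 to 48536114). Mir1a-1 is on chromosome 2 from 180389048 to 180389124, between genes, and Mir1a-2 on chromosome 18 from 10785481 to 10785552. Mir29a is on chromosome 6 from 31062660 to 31062747, between genes. Mir193b is on chromosome 16 from 13449523 to 13449601 and Mir365-1 from 13453840 to 13453926. Mir423 is on chromosome 11 from 77078064 to 77078172 in an intron of Nsrp1. Mir126a is on chromosome 2 from 26591357 to 26591429 in Egfl7, with Mir126b on the other strand from 26591363 to 26591420. Mir486 is on chromosome 8 from 23142555 to 23142682 in an intron of Ank1. Mir375 is on chromosome 1 from 74900658 to 74900721, between genes.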

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

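Of the tests in this part, those of arm bases, low counts, pool, miR-378a-3p share, depth slopes, miR-122-5p difference and marker shares were chosen only after the result was seen, while the tests of the difference and the splits of the samples were planned.

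Single libraries stood far from the other 4 of their group in 17 of 82 sets of 5 values, by the gap to the next value over the range (Dixon's ratio). Independent normal values would do so in about 1 in 20 sets. These values were not logged and the sets share libraries, so the 17 cannot be compared with that rate. In total counts the library that stood apart was hypothalamus input 5 (5562487, next 1326583). In CPM of mmu-miR-122-5p it was hypothalamus input 4 (17083), of mmu-miR-1a-3p hypothalamus input 4 (178996), liver IP 4 (15719) and, as the lowest, muscle IP 5 (453277), and of mmu-miR-378a-3p hypothalamus input 4 (11232). For mmu-let-7a-5p muscle input 1 (1245, next 1047) and muscle IP 5 (66180) stood apart, and liver IP 4 for mmu-miR-423-5p (8467), mmu-miR-5119 (2140) and mmu-miR-6236 (3912). mmu-miR-193b-3p was highest in brown fat input 5 (1283) and in brown fat IP 4 (176, next 43.6), and mmu-miR-365-3p in brown fat input 5 (2605). In the hypothalamus, mmu-miR-375-3p, a miRNA of endocrine cells, was highest in IP 5 (96614, next 372), mmu-miR-9-5p in IP 3 (25103, next 13619) and mmu-miR-124-3p in input 3 (14379, next 5068).

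The change of IP against input differed between brown fat and liver for 26 miRNAs, muscle for 68 and hypothalamus for 145. Against liver these included miR-455-5p (4.04; 2 counts in the liver IPs), miR-379-5p (2.64), miR-378a-3p (2.33), miR-5099 (2.23), let-7i-5p (1.90) and miR-6236 (-3.55). Against muscle they included miR-182-5p (6.96; 0 counts in the muscle IPs), miR-30b-5p (4.42; 1 count, 9.32 without muscle IP 4), miR-210-3p (3.30; 1 count, 8.15 without muscle IP 3), miR-30e-5p (3.82), miR-30a-5p (2.83), miR-378a-3p (1.91), let-7e-5p (-2.74), let-7a-5p (-2.06), miR-423-5p (-1.90), miR-125a-5p (-1.53) and miR-486b-3p (-1.51). Against hypothalamus they included miR-101b-3p (1.90), miR-30e-5p (1.65), miR-101a-3p (1.55), miR-30a-5p (1.49), miR-5099 (1.44), miR-375-3p (-7.46), miR-219a-2-3p and miR-219b-5p, which share reads (-7.33 each; 0 counts in the brown fat IPs), miR-1224-5p (-7.28; 0 counts there) and miR-7b-5p (-6.19). Fitted values for groups with 0 to 3 counts depend on the prior count and are no bound. The miR-375-3p value was 2.57 without hypothalamus IP 5. Of 20 omissions of 1 library, 16 more ended its call, 17 that of miR-1224-5p and 13 that of miR-219a-2-3p, while against liver 18 ended that of let-7i-5p, 12 of miR-5099 and 7 of miR-455-5p (9.95 without liver IP 3), and against muscle 7 of miR-486b-3p and 3 of miR-182-5p. The other upward values against hypothalamus reached between 5.10 and 5.52 at most without 1 library. Without 1 library miR-219a-2-3p ran from -7.48 to -4.60 and miR-1224-5p from -7.69 to -4.33.

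Among 100 splits of the same libraries into groups of the same sizes, the real one included, 1 gave as many calls as the real split in each IP comparison. The real counts were 244 in brown fat, 149 in liver, 228 in muscle and 206 in hypothalamus, the highest of the other splits 0, 16, 0 and 1, and the highest among those that part as many mouse pairs 0, 6, 0 and 0. For the difference from liver (26) it was 1 split, with 0 as the highest other. For muscle (68) and hypothalamus (145) it was 2 splits each, with 231 and 161 as the highest others. The highest other split exchanged IP and input in all 10 brown fat libraries in both, and kept them in 8 of the 10 muscle and 4 of the 10 hypothalamus libraries. Splits of a difference mix in the IP effect of both tissues, which calls more miRNAs than the difference, so they cannot test it. Of the inputs 1 split each reached the real 290, 274, 269 and 376, with 243, 221, 245 and 287 as the highest others, from splits that kept 0, 2, 1 and 4 of the 5 libraries of the tissue. Such splits regroup libraries of 4 tissues that differ in many miRNAs, so high counts arise without parting the named tissue. The real split thus gave more calls than any other split drawn in the 4 IP and 4 input comparisons. As the other splits mix library types or tissues within a group, this shows only that the labels carry a difference. It does not measure how many calls are right or what caused them. For the 3 differences chance was not tested.

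The IP against input changes were correlated between the 4 tissues, including the remote ones, in which activity of the Ucp1 driver was not measured. Low counts in the IPs were argued against by an r of at least 0.88 between any pair of tissues among miRNAs of at least 1000 CPM, and RNA with the make-up of the brown fat IP filling most of the remote IPs by miR-378a-3p, whose highest remote mean was 3.77% of its brown fat IP mean (4.95% in the highest library); a smaller share stays open. Across 148 of the 156 miRNAs, the mean change went with guanine in the hairpin arm (rho 0.24, permutation p = 0.0034, adjusted over 4 bases 0.0068). It went against adenine (rho -0.26, permutation p = 0.0017, adjusted 0.0068), with -0.05 for cytosine. The permutation treats the entries as independent, but let-7 arms are related and entries that share reads were kept. Of these, miR-1a-3p and miR-1b-5p had guanine fractions of 0.257 and 0.082. The p-values may thus be too small, and the relations are weak. Sequence-dependent capture or ligation stays a candidate that these values cannot decide. Uridine, the base that 4TU labelling replaces, had a rho of 0.02 (permutation p = 0.85), which cannot tell, since the arms were longer than the miRNAs and the labelled share is unknown. The pool cannot be told apart from the type, with 0 inputs in the pool of the IPs, and labelling in all tissues by uridine salvage without UPRT was not tested.

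miR-122-5p and miR-1a-3p, of liver and muscle, were found in the IPs of tissues not known as their source. For miR-1a-3p in the liver IP, counts stayed at 125 to 191 while totals ran from 11928 to 444006 (slope of log2 count on log2 total -0.03, SE 0.07), so a constant number of reads carried into each library may explain it. For miR-122-5p in the brown fat IP counts followed the total (slope 1.01, SE 0.28), which argues against a constant number, and in the muscle IP the slope of 1.34 (SE 0.79) cannot tell. A change of miR-122-5p itself of the same size in each IP stays open, as its change in brown fat minus that in liver was 1.46 (SE 0.57, adjusted p = 0.103), though 1.57 with adjusted p = 0.00317 with total count. Transfer of these miRNAs between tissues in the mice was not tested. The design labels RNA made where the driver is active, so it does not by itself account for a pull-down of miRNAs brought from liver or muscle.

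Hypothalamus input 4 held a larger share than each of the other 4 inputs of 6 of 6 miRNAs of other tissues: 72.3 times the next for miR-1a-3p, 89 for miR-133a-3p, 59.7 for miR-206-3p, 52.9 for miR-122-5p, 6.07 for miR-192-5p and 5.38 for miR-378a-3p. Material of muscle, liver and perhaps other tissues in that library is a candidate explanation. A constant number of carried-over reads was argued against for the muscle miRNAs, whose counts were 2.53, 2.45 and 2.07 times the highest count in the other inputs (miR-1a-3p, miR-133a-3p and miR-206-3p; 27393 against 10839 for the first). For the others it stays open, as miR-122-5p was at 1.45 times and miR-192-5p and miR-378a-3p at 0.195 and 0.298 times, within the range of the other inputs. The design gives no biological explanation for a single library.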

How the results depend on the processing

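The rescaling to equal medians, shared entries counted once and the removal of hypothalamus input 4 and liver IP 4 were chosen after the results were seen. The IP against input counts stayed within 1.5 times the reported ones in 9 of 10 alternatives in brown fat, 10 of 11 in liver, 9 of 10 in muscle and 8 of 11 in hypothalamus; without a filter more miRNAs were tested and 401, 235, 345 and 391 were called, and in hypothalamus 311 with a minimum of 10 CPM and 329 in the fit of all 40 libraries. Leaving out 1 library gave 239 to 259, 147 to 172, 167 to 260 and 202 to 223. The inputs gave 268 to 306, 255 to 296, 249 to 278 and 368 to 394 without 1 library, and only hypothalamus without a filter (596) left the range. The difference from liver gave 4 calls with RLE, 5 without a filter, 4 at 10 CPM, 0 with all 40 libraries, 6 with equal medians, 12 with shared entries once, 2 without the doubted libraries and 1 to 32 without 1 library. That from muscle gave 20 with all 40 libraries and 45 to 75 without 1 library, and that from hypothalamus 59 with RLE, 42 with total count, 94 without a filter, 92 with DESeq2, 66 with all 40 libraries, 53 with equal medians and 115 to 197 without 1 library. The choice of the TMM reference library alone moves the difference from liver by -1.05 to 0.56, from muscle by -0.62 to 1.12 and from hypothalamus by 0 to 3.57, which is enough to turn the sign of their medians (0.85, 0.53 and -1.30). With the mouse as a replicate block the IP counts were 242, 148, 227 and 210, and no count moved by more than 1.5 times. The brown fat list medians kept their sign and stayed uncalled in all alternatives (liver -3.52 to -1.10, muscle -2.91 to -1.31, hypothalamus -4.06 to -1.06; lowest adjusted p 0.335, 0.198 and 0.335) and without 1 library (-2.40 to -1.22, -2.54 to -2.01 and -2.17 to -1.12). These values changed sign: in the hypothalamus IP miR-122-5p (2.17 with the replicate block, 2.85 with limma-voom, 2.86 without input 4 or the doubted libraries), miR-1a-3p (0.07, 0.21 and 0.82) and miR-206-3p (2.04, 2.63 and 3.31), with ranges without 1 library of -2.41 to 2.86, -4.65 to 0.82 and -1.62 to 3.31; miR-7b-5p there with total count (-0.34) and no filter (-0.35; range -0.59 to 1.10); with total count miR-541-5p in the liver IP (-0.28) and miR-1a-3p in the muscle IP (-0.14); without 1 library miR-128-3p in the brown fat IP (-0.31 to 0.22) and miR-146a-5p in the muscle IP (-0.43 to 0.04). In the difference from muscle these were miR-122-5p (-2.07 to 0.29 without 1 library) and miR-1a-3p (-0.07 to 0.89; -0.61 with equal medians), and in that from hypothalamus miR-122-5p (-0.30) and miR-1a-3p (-0.63) with the replicate block and miR-375-3p without hypothalamus IP 5 (2.57; range -7.60 to 2.57). In the inputs it was miR-148a-3p with total count in brown fat (0.91; 0.38 with the replicate block, -0.22 to 0.02 without 1 library) and hypothalamus (0.83). Of 2955 values of the miRNAs with the largest changes and others printed in the text, without 1 library 2708 kept direction and call, 153 lost and 76 gained the call and 18 changed sign, and of 2077 under the other alternatives 1907, 85, 66 and 19. Among all miRNAs the naming rule selects, these changed sign without 1 library: 1 of 50, 1 of 51, 2 of 45 and 7 of 47 in the IP comparisons, 12 of 39, 6 of 44 and 25 of 43 in the differences, and 3 of 41, 2 of 39, 2 of 39 and 2 of 41 in the inputs. Depth limits the IPs of liver and hypothalamus most, where libraries of 11928 and 67819 counts can show 252 and 44.2 CPM at 3 counts.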

Other observations

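The test of the other input-built lists was planned, and the miRNA singled out was chosen after its values were seen. Lists of liver, muscle and hypothalamus miRNAs served as a comparison for the brown fat lists, and camera called none of them. In the brown fat IP the liver list had 13 members higher and 12 lower of 29 (adjusted p = 0.313), muscle 10 and 21 of 44 (0.428) and hypothalamus 19 and 36 of 63 (0.265). Of the 13, let-7a-5p, let-7b-5p, let-7b-3p, let-7f-5p, let-7g-5p, miR-423-5p, miR-5099, miR-3963 and miR-92a-3p were higher in all 4 IPs. The others were miR-122-5p, miR-671-3p, miR-21c and miR-28a-3p. These rises, and the score per mouse given below, thus do not by themselves show an excess of liver miRNAs in brown fat. In the liver IP muscle had 6 and 2 of 11 (0.265), the 6 being 4 miR-486 entries and miR-1a-3p with miR-1b-5p, which share reads within each set, and hypothalamus 7 and 20 of 40 (0.265). In the muscle IP liver had 6 and 5 of 13 (0.428) and hypothalamus 12 and 42 of 65 (0.265), and in the hypothalamus IP liver had 6 and 9 of 27 (0.638) and muscle 5 and 17 of 30 (0.428). Without hypothalamus input 4, which stood apart in miRNAs of muscle and liver, these were 7 and 10 of 28 and 6 and 14 of 30. The hypothalamus list had 3 or 4 higher and 20 to 27 lower in the liver IP without any liver input, and 9 or 10 and 22 or 23 of 39 in the muscle IP without any muscle input. fry called 9 of the 12 input-built lists on balance one way and all 12 in either direction. Adjusted over the list alone the counts differed for liver in brown fat (14 and 12) and in hypothalamus (6 and 8). The score per mouse minus that of all miRNAs was above 0 in all 5 mice for the muscle list in liver (1.59 ± 0.77) and the liver list in muscle (0.89 ± 0.29) and in all 4 paired mice for the liver list in brown fat (0.92 ± 0.31). It was above 0 in 3 of 5 for the liver list in hypothalamus (-0.10 ± 0.51) and in no mouse for the others: the hypothalamus list in brown fat (-0.76 ± 0.14), liver (-0.73 ± 0.37) and muscle (-0.53 ± 0.13), and the muscle list in brown fat (-0.37 ± 0.18) and hypothalamus (-0.57 ± 0.50). Of the brown fat list in the muscle IP, mmu-miR-193b-5p rose from 0.732 to 41.7 CPM (6.44, SE 0.40, adjusted p = 1.19e-12), where the brown fat IP held 147 ± 57.6 CPM (SD, n = 5), and its rise there was 3.91 (SE 0.30). The other arm of the hairpin, miR-193b-3p, also on that list, had -0.63 in the muscle IP (adjusted p = 0.324), at 6.61 CPM in the input and 5.14 in the IP.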
